A study of Mus musculus with 31 samples.

How the data were processed

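Mouse embryonic fibroblasts infected with retroviruses for 4 factors (4F: Oct4, Sox2, Klf4 and c-Myc), 3 factors (3F: without c-Myc) or GFP were measured at times from day 0 to day 12. Per the labels' protocols, the cells grew in DMEM with fetal bovine serum, total RNA was isolated with on-column DNase treatment, and biotin-labelled sense targets were hybridized to Affymetrix single-colour mouse arrays. Per the labels, the replicate 1 arrays were labelled from 120 ng of RNA and the others from 300 ng. The deposited table holds log2 signals, 1 column per array and 1 row per probe set, with values from 4.27 to 14.3. The authors' method of normalization is not given in the sources used here. The 31 columns have nearly the same quartiles, with medians from 6.04 to 6.17. The values were used as deposited, with no further normalization. No raw files were read.

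Of 28853 rows, 21789 carry 1 gene symbol, 1621 several and 5443 none. The Entrez IDs of 21698 of these rows were found in the reference of gene names. Rows with 1 symbol gave 19938 genes, of which 999 had more than 1 row, and for these the row with the highest mean over all 31 arrays was used. Probe sets of close paralogs can share signal, which was not examined. The genome build is not named, so no coordinates are given.

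The arrays form 19 groups, 12 with 2 arrays and 7 with 1. The source description of the 3F samples speaks of 4 factors but names Oct4, Sox2 and Klf4 alone. They were taken as 3F, as their titles and descriptions say, so every 3F value rests on that reading. Samples titled day 0 of the 4F series had received no virus per the labels and serve as the uninfected start. Arrays of 1 number share a labelling batch per the labels, so the replicate number was taken to pair samples into a replicate 1 set (12 arrays), a replicate 2 set (12 arrays) and a set without number (7 arrays). The pairing was checked by correlating, across genes, the replicate differences of each pair of groups: in 66 pairs r lay between 0.081 and 0.69 (median 0.32), and 65 exceeded 0.1.

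Groups were compared with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 31 arrays (12 residual degrees of freedom, 2.68 prior). Its contrasts were 4F against GFP on days 1, 3, 5 and 8, their mean, day 8 minus day 1, and 4F or GFP against day 0. The 3F arm, with 1 array per day, was compared with 4F and with GFP in an additive model of day and arm over days 3, 5, 8 and 12 (18 arrays: 7 4F, 4 3F, 7 GFP; 12 residual degrees of freedom, 2.26 prior). Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes were called. In the group-mean model the p-values measure the spread between replicate arrays. In the additive model 3F has no replicates and its days serve in their place. The spread there also holds changes of the arm differences over days. The fit with the set as a term added the 3 sets to the additive model (10 residual degrees of freedom). In the group-mean model it separates only replicate 2 from replicate 1 (11 residual degrees of freedom), since arrays without number form groups of their own. All 3F arrays lie in the set without number. In the additive model this term therefore leaves 3F to be compared through its day 12 array alone. Single arrays were not tested, and list medians were ranked among 10000 random lists of the same size drawn from 50 bins of mean signal (seed 1).

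Gene lists were written from general knowledge before the data were examined, as were the comparisons, the tests, the named gene rule and most alternatives. There were 16 program lists (measured of written members): pluripotency network 39 of 42, epithelial 44 of 47, mesenchymal regulators 31 of 32, fibroblast matrix 38 of 41, contractile and serum response 27 of 28, cell cycle 49 of 50, p53 and senescence 30 of 33, nucleolar and MYC targets 52 of 54, cytosolic ribosomal proteins 31 of 41, glycolysis 19 of 22, oxidative phosphorylation 37 of 38, interferon 37 of 44, inflammatory 32 of 34, chromatin 34 of 35, cholesterol synthesis 17 of 22, and stress response 31 of 32. There were 11 cell type lists: keratinocyte 28 of 32, germ cell 22 of 23, trophectoderm and primitive endoderm 20 of 22, mesendoderm 17 of 18, neural 25 of 27, skeletal muscle 23 of 23, macrophage 24 of 24, endothelial 19 of 19, adipocyte 15 of 17, red blood cell 8 of 16, and chondrocyte and bone 14 of 17. Some genes stand in more than 1 list. A synonym was followed only where the written name is not itself the symbol of another gene, a rule corrected after a first run in which 3 names had matched another gene. Lists were tested with camera on the limma fits, with a preset correlation of 0.01 between genes and, as an alternative, an estimated correlation, and adjusted over the 27 lists within a comparison. Counts of members are given over all genes and adjusted over the list alone.

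Named genes are the 4 delivered factors, the 8 largest rises and falls per comparison (4F against GFP on days 1 and 8, 4F against 3F, 3F against GFP, GFP on day 8 against day 0) among called genes whose arrays did not overlap within any day, up to 4 called members per list with the largest change in these comparisons and in 4F on day 8 against day 0, and a fixed list in the 4F course, of which Cdkn1a and Gapdh had no usable row. From these the text gives examples. Members that moved against their list (Tbx3, Rybp, Lum, and Meox2, Slc16a1 or Cdh3 where the rule does not name them) were chosen after their values were seen.

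The steps were tested on simulated data with the layout of these arrays and the residual spread of each gene. The noise was independent, with no difference between sets or days and no correlation between genes. The shares of false calls therefore do not cover errors from these. Of genes changed by 0.5, 1 and 2 on the log2 scale, the day 8 contrast of 4F and GFP recovered 40.3, 82.1 and 93.9% (5 of 149 calls false), the mean of days 88.1, 98.5 and 100% (5 of 196), 4F against 3F 64.2, 91 and 100% (9 of 179) and 3F against GFP 68.7, 94 and 98.5% (9 of 183). Camera called a cell cycle list shifted by 0.3, and 1 other of 27 lists.

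Alternatives tried were the set as a term, quantile normalization, median centring, a filter at the 30th percentile of signal (5.46; 15299 genes kept, 4639 removed, 1 of them named in the text), the mean of a gene's rows, limma's trend and robust options, an absolute log2 change of at least 1, the arrays of the compared groups alone, other models and days for 3F, an estimated correlation for lists, and leaving out each array in turn. Left out of the tests were rows with several or no symbols, which were tested separately for 4F against GFP on day 8. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.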

Results

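Mouse embryonic fibroblasts were profiled on 31 single-colour expression arrays before infection (day 0) and up to day 12 after it. The cells had received retroviruses for Oct4, Sox2, Klf4 and c-Myc (4F), for the first 3 of these without c-Myc (3F), or for GFP as a virus control. There were 2 arrays each for day 0, for 4F on days 1, 2, 3, 4, 5, 6 and 8, and for GFP on days 1, 3, 5 and 8. There was 1 array each for 4F on days 10 and 12, GFP on day 12, and 3F on days 3, 5, 8 and 12, and these 7 groups have no replicates. Replicate 1 arrays were labelled from 120 ng of RNA and the other 19 arrays from 300 ng. The number of arrays limits the precision of every comparison. Values are log2 signals of 19938 named genes. Replicates of a group correlated across genes with Pearson r from 0.974 (4F day 8) to 0.993 (4F day 1), where genes are not independent replicates. The first principal component held 42.8% of the variance, with scores of 25.3 to 60.7 for the GFP arrays, 14.7 and 19 for day 0, -20.3 to 3 for 3F and -38.4 to 5.3 for 4F.

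The first question was what the 4 factors had changed 1 day after infection, against GFP virus on the same day. Genes for making ribosomes were higher in 4F, with 28 of 52 measured nucleolar and MYC target genes past the threshold. Among them were Dkc1, which modifies ribosomal RNA (1.19 ± 0.12, log2 difference ± SE, 2 arrays per arm, limma adjusted p = 0.00015), Ppat of purine synthesis (1.31 ± 0.15) and the RNA polymerase I subunit Polr1b (1.24 ± 0.22). The list's median was 0.72 (0.86 between the replicate 1 arrays and 0.53 between the replicate 2 arrays), with a camera adjusted p of 1.6e-48, and 0.015 with an estimated correlation between members. Adjusted over the list alone, 42 members passed. The difference holds a lower GFP signal too. In log2 signal Dkc1 stood at 9.293 on day 0, 9.635 in 4F and 8.443 in GFP, and Ppat at 9.213, 9.66 and 8.348. For both, GFP lay further from day 0 than 4F did. Furthest above GFP were Tmem229b, a membrane protein (3.11 ± 0.23, adjusted p = 8.6e-06), Akr1c18, which inactivates progesterone (2.75 ± 0.47, adjusted p = 0.01), Anxa10 (2.71 ± 0.56), the angiopoietin receptor Tek (2.26 ± 0.26) and the ephrin receptor Epha7 (2.06 ± 0.25). Furthest below it were the chemokine Cxcl12 (-1.63 ± 0.33, adjusted p = 0.023), the Wnt agonist Rspo2 (-1.42 ± 0.22), the lipid receptor S1pr3 (-1.4) and the collagen receptor Itga11 (-1.32). In limma, 361 genes passed an adjusted p of 0.05, 283 higher and 78 lower in 4F. All 361 went the same way between both pairs of arrays, but the call rests on these same pairs, so this is no separate support. With the set of arrays as a term in the fit, 924 passed. The count was 40 without 4F day 1 replicate 1, 39 without 4F day 1 replicate 2 and 23 without GFP day 1 replicate 1.

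Other lists moved on day 1 mostly as small shifts of many members. Of 49 cell cycle genes, 4 were higher (14 adjusted over the list alone), all of them for DNA replication: Mcm10 (0.95 ± 0.15, adjusted p = 0.0066), Mcm3 (0.85), Mcm7 (0.78) and Cdc6 (0.68 ± 0.12). The cell cycle median was 0.55 (0.7 and 0.36 within the sets; adjusted p = 9.5e-19, and 0.3 with an estimated correlation). Of 38 fibroblast matrix genes 1 was lower (2 over the list alone), the collagen gene Col5a1 (-0.89 ± 0.21, adjusted p = 0.049), with a list median of -0.53 (-0.7 and -0.31 within the sets; adjusted p = 2.6e-10, and 0.3 with an estimated correlation). Of 31 mesenchymal regulators 1 was lower (2 over the list alone), Snai1, which represses epithelial genes (-0.94 ± 0.21, adjusted p = 0.036), with a median of -0.33 (-0.41 and -0.19 within the sets; adjusted p = 7.4e-05, and 0.3 with an estimated correlation). Of 34 chromatin genes, Chaf1b (0.82) and the histone methyltransferase Ezh2 (0.61) were higher (8 over the list alone; median 0.3, with 0.44 and 0.22 within the sets, adjusted p = 5.9e-07, and 0.3 with an estimated correlation). No cholesterol synthesis gene passed over all genes, while 7 of 17 were lower over the list alone (median -0.6, adjusted p = 1.5e-07, and 0.3 with an estimated correlation). The contractile list (median -0.41, adjusted p = 0.0016, and 0.69 with an estimated correlation), the interferon list (median -0.32, with -0.44 and -0.1 within the sets, adjusted p = 0.047, and 0.93 with an estimated correlation) and the inflammatory list (median -0.16, adjusted p = 0.047, and 0.69 with an estimated correlation) also shifted down, with 0, 0 and 1 members past the threshold. Pluripotency genes had a median of -0.04 and a mean of 0.03 (adjusted p = 0.83), and their 2 called members, Rif1 (1.12) and Mybl2 (0.96), act in DNA replication and the cell cycle. Epithelial genes had a median of 0.01 (adjusted p = 0.66), with the junction receptor Cxadr higher (0.98) and the cadherin Cdh3 lower (-1.19). With the set as a term, oxidative phosphorylation genes (median 0.07) and chondrocyte and bone markers (-0.17) passed as well. Their camera adjusted p was 0.046 each, against 0.066 each without the set, and 0.62 and 0.47 with an estimated correlation.

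By day 8 the fibroblast programs lay far below the GFP control. Of 38 matrix genes, 37 were lower (37 over the list alone). Among them were Postn, a matrix protein of migrating fibroblasts (-4.41 ± 0.37, 2 arrays per arm, adjusted p = 7.2e-07), the collagen binder Lum (-4.52 ± 0.63), and Col1a1, the main collagen of fibroblasts (-2.46 ± 0.24, adjusted p = 2.5e-06). The matrix median was -2.51 (-2.23 and -2.76 within the sets; camera adjusted p = 9.3e-27, and 0.022 with an estimated correlation). Of 31 mesenchymal regulators 26 were lower (28 over the list alone), among them Cdh11, a cadherin of mesenchymal cells (-3.24 ± 0.23, adjusted p = 1.8e-07), the matrix protease Mmp3 (-4.55 ± 0.71) and Snai1 (-1.82 ± 0.21), with a median of -1.6 (adjusted p = 8.3e-16, and 0.02 with an estimated correlation). The homeobox gene Meox2 was higher (2.0). Of 32 inflammatory genes 19 were lower than in GFP (22 over the list alone; median -1.71, adjusted p = 8e-10, and 0.054 with an estimated correlation). They included Cxcl12 (-4.39), Saa3 of the acute phase (-4.29) and the eosinophil attractant Ccl11 (-4.04). Of 27 contractile genes 10 were lower (12 over the list alone, where 1 was higher), such as Tpm1 of actin filaments (-1.62 ± 0.28), with a median of -0.96 (-0.27 and -1.54 within the sets; adjusted p = 0.00097, and 0.7 with an estimated correlation). Furthest below GFP were the protease inhibitor Serpina3n (-5.85 ± 0.5, adjusted p = 8.4e-07), the chemokine Cxcl5 (-5.52 ± 0.43, adjusted p = 3.8e-07), and the matrix genes Aspn (-5.35 ± 0.56) and Dpt (-5.1 ± 0.49). Serpina3n, Dpt, Aspn and Saa3 all rose in GFP, and of these only Aspn lay below day 0 in 4F. Against day 0 Serpina3n stood at 0.06 in 4F and 5.91 in GFP, Dpt at 0.66 and 5.76, Aspn at -1.75 and 3.6, and Saa3 at 2.58 and 6.87. In limma 5497 genes passed the threshold, 2900 higher and 2597 lower in 4F. Of them 5496 went the same way between both pairs of arrays, which the call from these same pairs nearly ensures.

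Genes of growth, energy supply and the pluripotent state were higher than in GFP on day 8. Of 49 cell cycle genes 48 were higher (48 over the list alone), for example Uhrf1, which maintains DNA methylation at replication (2.66 ± 0.21, adjusted p = 5.2e-07), and the spindle checkpoint kinase Bub1 (2.57). The cell cycle median was 1.83 (2.21 and 1.41 within the sets; adjusted p = 2e-28, and 0.08 with an estimated correlation). Of 52 nucleolar genes 46 were higher (50 over the list alone; median 1.19, adjusted p = 2.5e-28, and 0.022 with an estimated correlation). Ppat (2.77 ± 0.15) and Dkc1 (2.4 ± 0.12, adjusted p = 1.9e-08) were among them. Against day 0 the cell cycle and nucleolar medians were 0.02 and -0.04 in 4F and -1.73 and -1.26 in GFP. For these 2 lists the difference therefore lay mostly in a fall in GFP. Of 39 pluripotency genes 22 were higher (23 over the list alone). They included the growth factor Gdf3 (2.69 ± 0.22, adjusted p = 5.7e-07), the nuclear receptor Nr0b1 (2.77 ± 0.54, adjusted p = 0.0012), Dppa5a (2.51 ± 0.35) and the transcription factor Nanog (1.84 ± 0.32, adjusted p = 4e-04), while Tbx3 was lower (-0.7). The pluripotency median was 0.57, 0.38 between the replicate 1 arrays and 1.16 between the replicate 2 arrays (adjusted p = 9e-09, and 0.22 with an estimated correlation). Of 44 epithelial genes 23 were higher (25 over the list alone), among them the adhesion molecule Epcam (2.76 ± 0.72, adjusted p = 0.0085), Spint2 (2.1 ± 0.31) and the desmosome gene Dsp (2.04 ± 0.23, adjusted p = 1.2e-05), while Cdh3 was lower (-2.0). The epithelial median was 0.61 (0.14 and 0.85 within the sets; adjusted p = 1.7e-06, and 0.26 with an estimated correlation). Of 19 glycolysis genes 14 were higher (15 over the list alone; median 0.99, adjusted p = 8e-10, and 0.02 with an estimated correlation). Besides the aldolase Aldoc, the lactate exporter Slc16a3 (3.6) and the glucose transporter Slc2a3 (3.46) were among them, and the monocarboxylate transporter Slc16a1 was lower (-1.61).

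Respiratory, chromatin and ribosomal protein genes were higher than in GFP as well. Against day 0 the medians of these lists were 0.2, 0.25 and 0.12 in 4F and -0.34, -0.55 and -0.2 in GFP. For glycolysis genes they were 0.41 in 4F and -0.68 in GFP, so part of each difference lay in a fall in GFP. Of 37 oxidative phosphorylation genes 26 were higher (33 over the list alone; median 0.56, adjusted p = 8.8e-11, and 0.02 with an estimated correlation), for example the cytochrome gene Cyc1 (1.21). Of 34 chromatin genes 23 were higher (25 over the list alone; median 0.97, adjusted p = 8.5e-13, and 0.022 with an estimated correlation), such as the remodeler Hells (2.64), and the polycomb partner Rybp was lower (-0.77). Of 31 cytosolic ribosomal protein genes 7 were higher (7 over the list alone; median 0.32, with 0.42 and 0.18 within the sets, adjusted p = 0.00012, and 0.25 with an estimated correlation), such as Rpl14 (1.07). Furthest above GFP were Akr1c18 (4.84 ± 0.47, adjusted p = 2.5e-06), the neural adaptor Bex1 (4.25 ± 0.39), the tubulin regulator Stmn2 (3.95 ± 0.62), the calcium binder Necab1 (3.95 ± 0.22, adjusted p = 3.1e-08), the transferrin receptor Tfrc (3.92 ± 0.34), the glycolytic aldolase Aldoc (3.78 ± 0.48), the Nodal co-receptor Tdgf1 (3.68 ± 0.53) and the transcription factor Foxd1 (3.66 ± 0.28). Some of these differences lay mostly in GFP. In log2 signal Tfrc was 9.86 on day 0, 9.974 in 4F and 6.056 in GFP, and Stmn2 9.098, 9.916 and 5.963. The remodeler Hells went from 9.001 on day 0 to 6.498 in GFP. Others lay in 4F, such as Aldoc (6.063, 10.09 and 6.303) and Tdgf1 (5.691, 9.339 and 5.658).

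The remaining 15 lists did not shift as a whole on day 8 (smallest camera adjusted p = 0.082, macrophage markers), though single members moved far. Brackets give the counts over the list alone and the median. Of 30 p53 and senescence genes 6 were higher and 5 lower (6 and 5 over the list alone; median -0.1), the lower ones led by the growth factor binders Igfbp5 (-3.27) and Igfbp3 (-2.8) and the cell cycle inhibitor Cdkn2b (-2.24). Of 31 stress response genes 6 were higher and 5 lower (8 and 5; median 0.15), with the amino acid transporter Slc7a3 (3.21) and the serine and glycine enzyme Shmt2 (1.91) highest. Of 37 interferon genes 2 were higher and 1 lower (1 and 1; median 0.18, but -0.47 between the replicate 1 arrays and 0.72 between the replicate 2 arrays): the antiviral enzyme Oas2 (2.06 ± 0.67, adjusted p = 0.03), Cmpk2 (1.0) and Ifit2 (-0.69). Of 17 cholesterol synthesis genes Stard4 (0.71) and Dhcr7 (0.67) were higher (1 over the list alone; median 0.26). Of 25 neural markers 4 were higher and 3 lower (4 and 3; median -0.01, mean 0.27, test upward), with Stmn2, the fatty acid binder Fabp7 (2.24) and the filament genes Nes (1.69) and Nefl (1.07) highest. Of 24 macrophage markers 1 was higher, the lysosomal gene Laptm5 (2.58), and 5 lower (1 and 5; median -0.15), such as the lysozyme gene Lyz2 (-1.87). Of 17 mesendoderm markers 3 were higher (3; median -0.13, mean 0.08, test downward), led by the chemokine receptor Cxcr4 (2.02). Of 20 trophectoderm and primitive endoderm markers 2 were higher and 2 lower (2 and 2; median -0.05), among them Tfap2c (1.04) and Gata6 (-1.16). Of 28 keratinocyte markers 3 were higher and 1 lower (2 and 0; median 0.03), such as Krt17 (0.83) and Serpinb2 (-1.18). Of 22 germ cell markers 2 were higher and 1 lower (2 and 1; median 0.02), among them the receptor Kit (0.69). Endothelial markers gave Tek (1.5) and the growth factor receptor Flt1 (-1.94) of 19 (1 and 1; median -0.09), adipocyte markers the lipase Lpl (-4.14) and Scd1 (0.89) of 15 (1 and 1; median -0.06), and red blood cell markers the embryonic globin Hbb-y (2.58) of 8 (1 and 0; median -0.02, mean 0.27, test upward). Of 23 skeletal muscle markers Mef2c was higher (0.81; none over the list alone; median -0.03, mean 0.04, test downward). Of 14 chondrocyte and bone markers 1 was higher, the phosphatase Alpl (1.78), and 3 lower (1 and 3; median -0.08), with Mgp (-2.5) and Comp (-2.24).

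How the difference from GFP grew with time was read from days 3 and 5 and from a test of day 8 against day 1. Against GFP, 29 of 38 matrix genes were lower on day 3 and 36 on day 5 (medians -1.76 and -2.35), as were 20 and 24 of 31 mesenchymal regulators (-0.92 and -1.32). Cell cycle genes were higher in 8 of 49 on day 3 and 39 on day 5 (0.46 and 1.13), and nucleolar genes were higher in 16 and 41 of 52 (0.33 and 0.82). Pluripotency genes were higher in 8 and 10 of 39 on these days (-0.05 and 0.22). Over all genes 2378 passed on day 3 (1252 higher, 1126 lower) and 4265 on day 5 (2098 higher, 2167 lower). Day 3 gave 3749 with the set as a term. The day 3 count was 1181 without 4F day 3 replicate 1 and 1134 without GFP day 3 replicate 1, and the day 5 count was 2427 without 4F day 5 replicate 1. Averaged over days 1, 3, 5 and 8, 8 arrays per arm, 7464 genes passed, 3743 higher and 3721 lower. Of them 7461 went in the same direction within both sets, which the call from these same arrays nearly ensures. In this average all 38 matrix genes were lower (median -1.75), 49 of 52 nucleolar and 48 of 49 cell cycle genes higher (0.74 and 1.03), and 14 pluripotency genes higher and 2 lower (0.18). The difference itself changed between day 1 and day 8 for 1693 genes in limma (2820 with the set as a term, 922 without 4F day 1 replicate 2). Fbxo15, a target of Oct4 and Sox2, went from -0.14 on day 1 to 2.34 on day 8, Foxd1 from 0.02 to 3.66, and Serpina3n from -0.21 to -5.85, while Anxa10 went from 2.71 to -0.09.

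**Figure D1:**
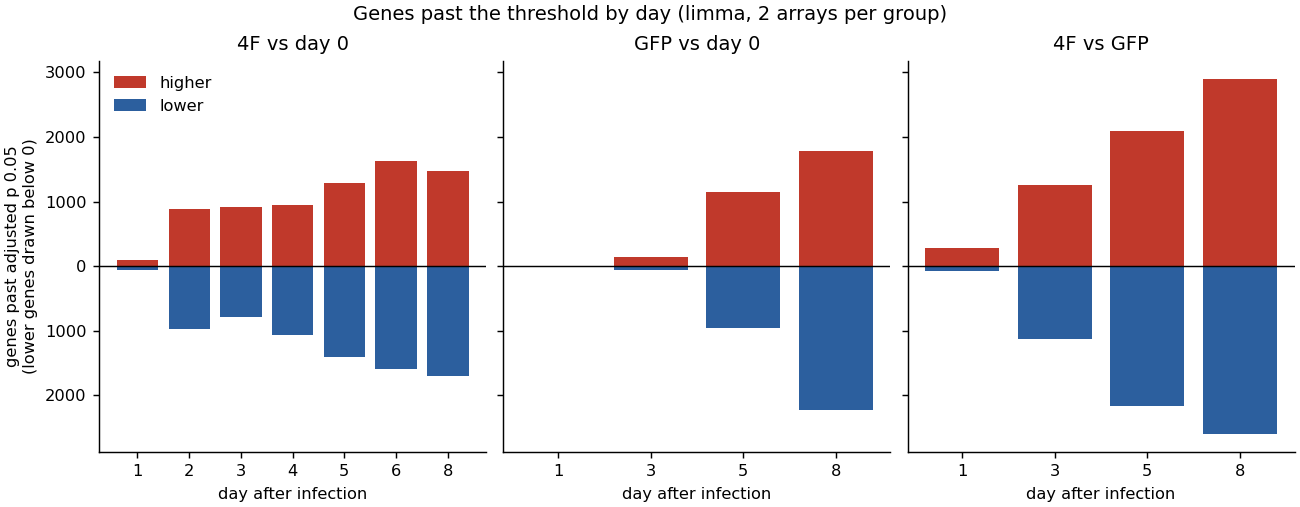
Number of genes past an adjusted p of 0.05 by day after infection, drawn above 0 for genes that were higher and below 0 for genes that were lower, for 4F against day 0, GFP against day 0 and 4F against GFP (2 arrays per group). Between 4F and GFP the counts went from 361 on day 1 to 5497 on day 8.

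The course of the 4F cells themselves was followed against the uninfected fibroblasts of day 0. Of the mesenchymal regulators 14 of 31 were lower on day 2, and of the matrix genes 16 of 38, against 21 and 22 on day 8. Pluripotency genes were higher in 4 of 39 on day 2, 6 on day 5, 13 on day 6 and 24 on day 8, and epithelial genes in 4, 6, 9 and 19 of 44. Contractile genes were lower in 15 of 27 on day 2, 6 on day 3 and 15 on day 8. These are counts, and the timing of lists was not tested. Over all genes, limma gave 167 on day 1 (102 higher, 65 lower), 1864 on day 2, 1700 on day 3, 2007 on day 4, 2702 on day 5, 3214 on day 6 and 3169 on day 8 (1473 higher, 1696 lower). Of the genes past the threshold on days 1 to 6, 129, 1440, 1300, 1653, 2123 and 2424 passed in the same direction on day 8, and 3, 5, 5, 2, 2 and 0 in the opposite one. All these comparisons share the 2 day 0 arrays, so agreement in direction is in part built in. The counts of days 1 to 4 were 369, 2879, 2733 and 3087 with the set as a term. With 2 arrays per group these counts depended on single arrays. Without MEF day 0 replicate 1 they were 29, 1054, 872, 1201, 1733 and 2066 on days 1 to 6. Without MEF day 0 replicate 2 they were 61, 1109, 1118, 1218 and 1733 on days 1 to 5, and 1958 on day 8. Without replicate 1 of the 4F day in question they were 29, 999, 814, 1088 and 1507 on days 1 to 5, and without its replicate 2 they were 29, 1238, 1290 and 1795 on days 1, 2, 4 and 5.

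On day 8 against day 0 the 4F cells had gained pluripotency, epithelial, glycolysis and sterol genes and lost contractile and mesenchymal ones. In GFP some lists shifted the same way: cholesterol synthesis (median 0.48), contractile (-0.78), interferon (0.6), stress response (-0.38) and muscle genes (-0.27). The cholesterol synthesis list did not pass between 4F and GFP on day 8 (median 0.26, camera adjusted p = 0.19). Contractile genes fell in 15 of 27 (20 over the list alone; median -1.73, adjusted p = 3.7e-11, and 0.28 with an estimated correlation), led by Ankrd1 (-4.02 ± 0.85, 2 arrays per group, adjusted p = 0.0039) and the smooth muscle genes Tagln (-3.42 ± 0.65) and Cnn1 (-3.11). Mesenchymal regulators rose in 1 and fell in 21 of 31 (22 over the list alone; median -1.3, adjusted p = 2.8e-17, and 0.038 with an estimated correlation), the falls led by S100a4 (-3.08 ± 0.32) and the signal protein Wnt5a (-2.75). Matrix genes fell in 22 of 38 (24; median -1.25, adjusted p = 3.5e-12, and 0.27 with an estimated correlation), led by Tnc (-3.69 ± 0.38) and the collagen cross-linker Lox (-2.9), while Lum rose (2.11). Pluripotency genes fell in 1 and rose in 24 of 39 (24; median 0.66, 0.39 and 1.03 within the sets; adjusted p = 3.6e-12, and 0.27 with an estimated correlation), the rises led by Tdgf1 (3.65). Epithelial genes fell in 1 and rose in 19 of 44 (23; median 0.5, with 0.15 and 0.7 within the sets, adjusted p = 6.6e-08, and 0.28 with an estimated correlation), for example the tight junction gene Cldn4 (1.73). Glycolysis genes rose in 7 of 19 (8; median 0.41, adjusted p = 1.5e-07, and 0.057 with an estimated correlation), among them Aldoc (4.02), Slc2a3 (2.5) and Pdk1, which inhibits pyruvate dehydrogenase (2.09 ± 0.15). Cholesterol synthesis genes rose in 6 of 17 (11; median 0.76, with 0.9 and 0.4 within the sets, adjusted p = 7e-06, and 0.33 with an estimated correlation), such as Dhcr7 (1.4). Chromatin genes rose in 9 of 34 (11; median 0.25, adjusted p = 0.00028, and 0.3 with an estimated correlation), led by the DNA demethylase Tet1 (1.46). Interferon genes had a median of 0.64 with 2 higher and 1 lower (adjusted p = 0.0011, and 0.73 with an estimated correlation), but -0.03 between the replicate 1 arrays and 1.54 between the replicate 2 arrays. Smaller shifts were found for oxidative phosphorylation (median 0.2, adjusted p = 0.0012, and 0.28 with an estimated correlation), stress response (in the same order -0.35, 0.0029 and 0.37), macrophage (-0.18, 0.013 and 0.37) and muscle genes (-0.18, 0.006 and 0.63). Their medians within the replicate 1 and replicate 2 sets were 0.3 and 0.13, -0.48 and -0.23, -0.37 and -0.06, and -0.47 and 0.02, so the macrophage and muscle shifts lay mostly in the replicate 1 set. Cell cycle and nucleolar genes had medians of 0.02 and -0.04 against day 0 (adjusted p = 0.72 and 0.58). Inflammatory genes had a median of -0.15 (adjusted p = 0.21), with 3 higher and 4 lower: Saa3 (2.58 ± 0.52, adjusted p = 0.0027) and Ccl8 (2.29) rose in 4F against day 0, and Has2, which makes hyaluronan (-3.83), and Csf1 (-2.62) fell.

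**Figure D2:**
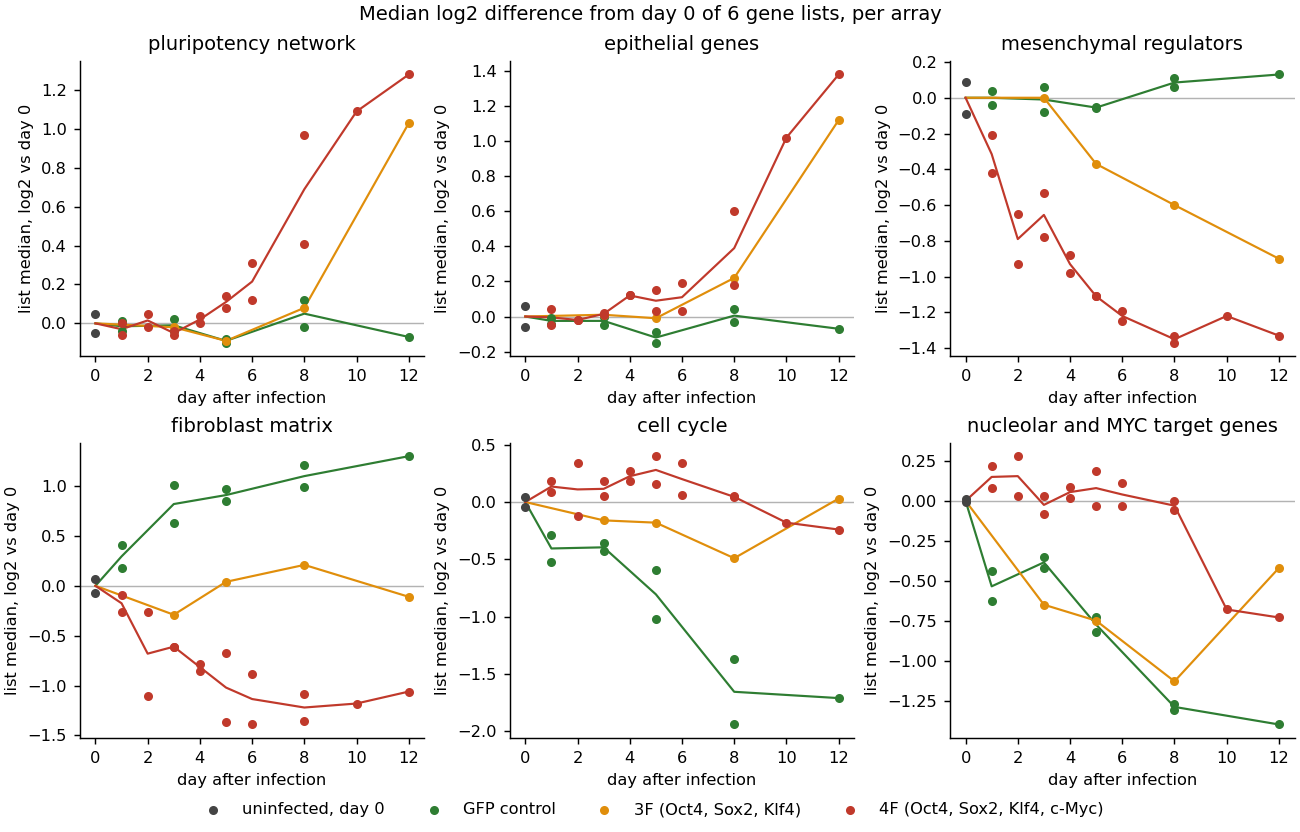
Median log2 difference from day 0 of the members of 6 gene lists, by day after infection; points are arrays and lines join group means of 4F, 3F and GFP. The cell cycle median stayed near day 0 in 4F (0.05 and 0.04 on day 8) and reached -1.94 and -1.37 in GFP.

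Genes fixed beforehand passed the threshold on different days, and differences in timing between them were not tested. Snai1 (log2 signal 8.6 on day 0, 7 on day 2) and the fibroblast surface protein Thy1 (10.25 and 8.45) were past the threshold as lower from day 2. So were Snai2 and Col1a1 (12.6 and 11.76), and Zeb1, another repressor of epithelial genes, from day 4. The first day past the threshold is not the first day of change, as Snai1 stood at 7.86 on day 1. Of the pluripotency genes followed individually, Fbxo15 was past the threshold from day 2 (4.75 to 5.55), and reached 2.33 ± 0.17 above day 0 on day 8 (adjusted p = 6.5e-07). Nanog and Dppa5a passed as higher from day 6 (2.08 ± 0.32, adjusted p = 0.00031, and 2.66 on day 8). Zfp42 (1.46), Sall4 (1.04), Utf1 (1.56), Cdh1, the epithelial cadherin (1.64 ± 0.38, adjusted p = 0.0068), and Epcam (2.64) passed on day 8. The mean Epcam signal was 5.53 on day 0 and already 7.38 on day 6. The pair of day 8 arrays differed for Nanog (7.15 and 8.48) and Epcam (6.67 and 9.68). The cell cycle inhibitor Cdkn2a passed as higher from day 4 (1.2 ± 0.2 on day 8, adjusted p = 0.00067), with 1.17 ± 0.2 in GFP (adjusted p = 0.00059), and 4F and GFP differed by 0.02 on day 8 (adjusted p = 0.95). Col3a1 passed as higher on day 2 alone (1.21), with 0.55 on day 8. Actin (Actb) was lower on 5 days (-0.52 on day 8). Not past the threshold on any day were Esrrb (0.5 on day 8), Lin28a (0.18), Krt8 (1.13, adjusted p = 0.051), Zeb2 (-0.56, adjusted p = 0.052), Twist1 (-0.15) and Tbp (0.13). In the fit with the set as a term Krt8 and Zeb2 passed on day 8 (adjusted p = 0.04 and 0.031), Cdh1 on day 6 (0.031), and Zeb1 and Cdkn2a from day 2 (0.043 and 0.0052).

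Signals named for the delivered factors differed in their course. Pou5f1, which encodes Oct4, passed the threshold as higher from day 5 (2.12 ± 0.4, adjusted p = 0.0021), with 3.54 ± 0.4 above day 0 on day 8 (adjusted p = 3e-05). Sox2 passed on day 8 (1.68 ± 0.33, adjusted p = 0.0026). Myc was lower than on day 0 on days 2 (-2.74, adjusted p = 0.033), 5 (-2.91, adjusted p = 0.018) and 6 (-2.94, adjusted p = 0.014), with -2.19 on day 8 (adjusted p = 0.065). The set as a term brought Myc past the threshold on days 3, 4 and 8 as well (adjusted p = 0.0072, 0.0034 and 0.0039). Klf4 did not pass on any day (-0.63 on day 8), except on day 2 with the set as a term (-0.84, adjusted p = 0.044). Against GFP on day 1 none of the 4 passed: Pou5f1 0.69, Sox2 0.45, Klf4 -0.43 and Myc -0.45. Against GFP on day 8 Pou5f1 (3.62 ± 0.4, adjusted p = 8.8e-06) and Sox2 (2.07 ± 0.33) were higher, Klf4 was lower (-0.92 ± 0.26, adjusted p = 0.014), and Myc differed by -0.99 (adjusted p = 0.4). Averaged over days 1, 3, 5 and 8 Myc differed by -0.9 (adjusted p = 0.076, and 0.0065 with the set as a term). These signals do not check the arm labels.

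**Figure D3:**
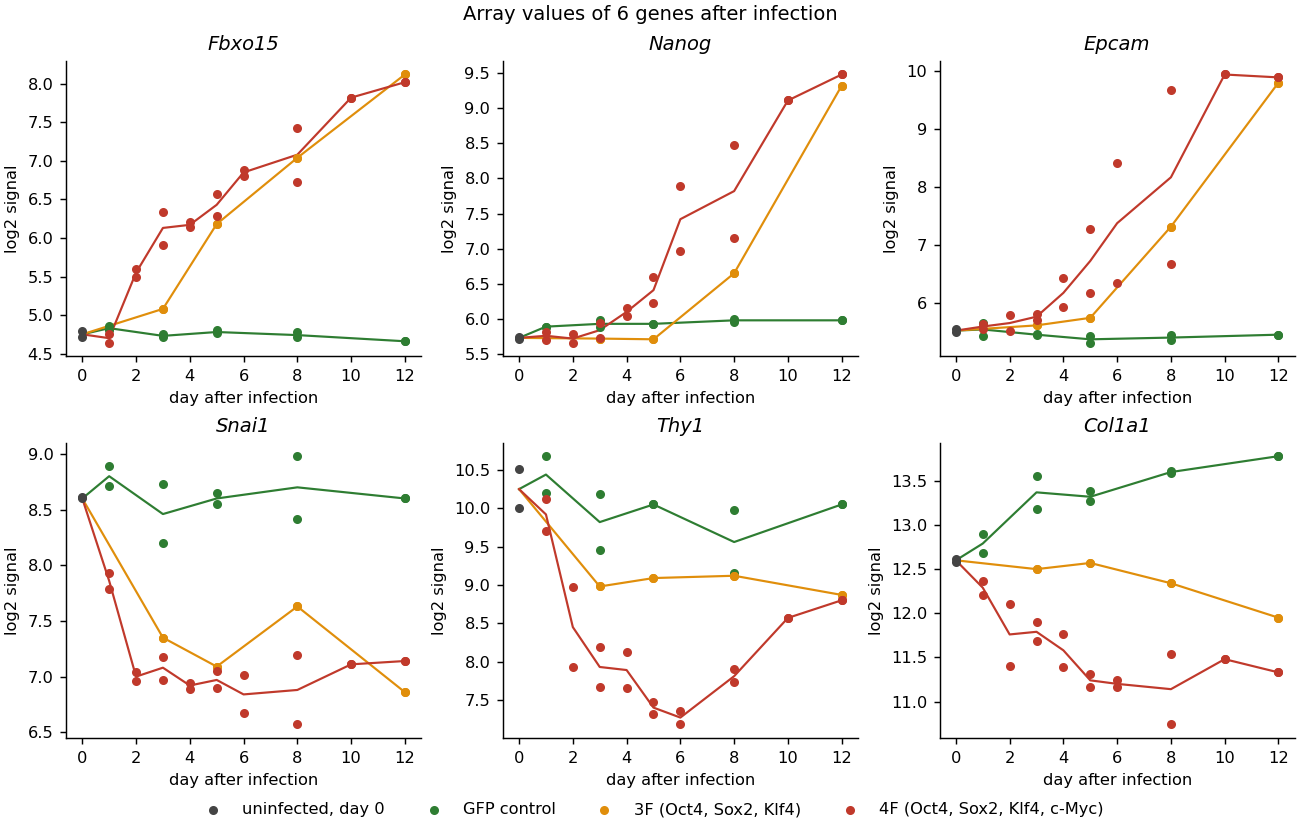
Log2 signal of Fbxo15, Nanog, Epcam, Snai1, Thy1 and Col1a1 by day after infection; points are arrays and lines join group means of 4F, 3F and GFP from the day 0 mean. In 4F, Thy1 went from 10.25 on day 0 to 7.27 on day 6 and 8.8 on day 12, and Fbxo15 from 4.75 to 8.02.

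The GFP arrays show what virus and time in culture changed without the factors. Cell cycle genes fell and matrix genes rose: by day 8, 47 of 49 cell cycle genes were lower (48 over the list alone; median -1.73, camera adjusted p = 2.9e-37, and 0.11 with an estimated correlation), among them the DNA precursor enzyme Rrm2 (-2.89 ± 0.38, 2 arrays per group, adjusted p = 8.6e-05). Nucleolar genes fell in 47 of 52 (48; median -1.26, adjusted p = 8.3e-39, and 0.036 with an estimated correlation), for example Dkc1 (-2.15 ± 0.12). Matrix genes rose in 26 of 38 (28; median 1.04, adjusted p = 1.4e-13, and 0.14 with an estimated correlation), with the proteoglycan Dcn (4.3 ± 0.41) and Col3a1 (2.95 ± 0.33). Inflammatory genes rose in 15 of 32 (19; median 1.24, with 0.75 and 1.51 within the sets, adjusted p = 7.7e-09, and 0.11 with an estimated correlation), with Saa3 (6.87 ± 0.52, adjusted p = 1.6e-06) the largest rise of all genes. For the other lists, brackets give the count over the list alone where there is one, the median, the adjusted p and that with an estimated correlation. Chromatin genes fell in 17 of 34 (19; median -0.55, adjusted p = 8.8e-08, and 0.11 with an estimated correlation), oxidative phosphorylation genes in 13 of 37 (16; -0.34, 9.4e-07, and 0.11) and glycolysis genes in 10 of 19 (10; -0.68, 0.0025, and 0.21), while Slc16a1 rose (2.19). Contractile genes fell in 6 of 27 (7; -0.78, but -1.38 and -0.15 within the sets; adjusted p = 0.00082, and 0.73 with an estimated correlation), stress response genes in 7 of 31 (9; -0.38, 0.00082, and 0.33) and muscle markers in 5 of 23 (7; -0.27, 0.015, and 0.73), such as Actc1 (-2.14). Cholesterol genes shifted up (2 of 17; 0.48, 0.0082, and 0.73), interferon genes too (1 of 37, Ifit3 at 1.58; median 0.6, 0.018, and 0.99), and ribosomal protein genes down (2 of 31; -0.2, 0.0082, and 0.63). Within the replicate 1 and replicate 2 sets the medians were -0.44 and -0.28 for stress response, -0.54 and -0.02 for muscle, 0.76 and 0.22 for cholesterol, 0.26 and 1.04 for interferon and -0.36 and -0.05 for ribosomal protein genes. Mesenchymal regulators had a median of 0 and a mean of 0.23, with 9 higher, such as Mmp3 (3.25), and 4 lower (adjusted p = 0.76). Pluripotency genes had a median of 0.08 and a mean of -0.02, with 3 lower (adjusted p = 0.98).

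Counts for GFP against day 0 were 18 on day 1 (8 higher, 10 lower), 210 on day 3, 2108 on day 5 and 4006 on day 8 (1778 higher, 2228 lower). Cell cycle genes were lower in 1, 1, 25 and 47 of 49 on these days, and nucleolar genes in 3, 2, 41 and 47 of 52. With the set as a term the first 3 counts were 143, 592 and 3446. Without MEF day 0 replicate 1 they were 3, 6 and 683, and without MEF day 0 replicate 2 they were 7, 96 and 1282. Without GFP replicate 1 of the day they were 3, 6 and 1047, and without GFP replicate 2 of the day 42, 571 and 965.

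What the 3 factors without c-Myc changed was tested against GFP over days 3, 5, 8 and 12 together, with 4 3F and 7 GFP arrays. The days stand in for replicates of 3F, which has 1 array per day. All 3F arrays belong to the set without number, which holds only the day 12 array of GFP. The arm is therefore almost wholly tied to the set, and a shift can come from either. With the set as a term, 3F is compared through its day 12 array alone. Matrix genes were lower and cell cycle genes higher in 3F than in GFP. Of 38 matrix genes 30 were lower (32 over the list alone; median -1.08, adjusted p = 1.6e-16, and 0.36 with an estimated correlation), for example Postn (-2.46 ± 0.24, adjusted p = 7.6e-06). Of 49 cell cycle genes 38 were higher (48; median 0.89, adjusted p = 2.4e-19, and 0.51 with an estimated correlation), for example Rrm2 (1.61 ± 0.32, adjusted p = 0.0029) and the proliferation marker Mki67 (1.51). For the other lists, brackets give the count over the list alone, the median, the adjusted p and that with an estimated correlation. Mesenchymal regulators were lower in 15 of 31 (18; -0.52, 6.6e-06, and 0.51), with Snai1 at -1.35 ± 0.16 (adjusted p = 5.8e-05), and Meox2 was higher (2.09). Epithelial genes were higher in 10 of 44 (10; 0.24, 4.2e-06, and 0.61), with Perp of the desmosome (2.72 ± 0.3) and Cxadr (1.9 ± 0.13), and Cdh3 was lower (-1.96). Pluripotency genes were higher in 8 of 39 (8; 0.29, 8.7e-05, and 0.63), with Gdf3 (2.62 ± 0.31, adjusted p = 5.1e-05), Fbxo15 (1.75 ± 0.32) and Tfcp2l1 (1.43 ± 0.26), while Nanog (0.68, adjusted p = 0.37) and Epcam (1.47, adjusted p = 0.13) did not pass. The 3F arrays of days 3, 5, 8 and 12 had pluripotency medians of -0.02, -0.09, 0.08 and 1.03 against day 0 and epithelial medians of 0.01, -0.01, 0.22 and 1.12, with the single day 12 array furthest from day 0. Chromatin genes were higher in 10 of 34 (15; 0.4, 4.2e-06, and 0.51). Interferon genes were lower in 1 and higher in 5 of 37 (5; 0.38, 0.00042, and 0.73), the higher ones with Oas2 (1.93; adjusted p = 0.076 with the set as a term). Inflammatory genes were lower in 8 of 32 and higher in 1 (10; -0.45, 0.00082, and 0.51), with Cxcl12 at -2.62 ± 0.3. Nucleolar genes were higher in 5 of 52 and lower in 1 (4; 0.21, 0.0035, and 0.84) with Ppat at 1.89, and oxidative phosphorylation genes were higher in 3 of 37 (2; 0.1, 0.0076, and 0.61). Macrophage markers shifted down (-0.14, 0.013, and 0.36; 0.069 with the set as a term), with Lyz2 (-1.66) lower and Laptm5 (2.57) higher. With the set as a term the contractile list (-0.18, adjusted p = 0.31) and the p53 list (-0.16, adjusted p = 0.31) passed as well, at 5e-04 and 0.01. The cholesterol list had a median of -0.06 and a mean of 0.05 (adjusted p = 0.62).

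In single genes the 3F arm differed most from GFP in Akr1c18 (7.05 ± 0.38, adjusted p = 3.8e-08), the BMP and Wnt antagonist Sostdc1 (6.08 ± 0.32), the aldehyde dehydrogenase Aldh3a1 (4.73), Sbspon (4.51), and the peptidase Dpp4 (4.46 ± 0.2, adjusted p = 9e-09). Furthest below GFP were the growth factor Gas6 (-2.99 ± 0.39, adjusted p = 1e-04), Tnmd (-2.91) and Mfap4 (-2.84). Gpr50 (3.87), Cyp7b1 (-2.7) and Mest (-2.68) lost the call with the set as a term (adjusted p = 0.058, 0.059 and 0.13). Pou5f1 was higher in 3F (2.08 ± 0.51, adjusted p = 0.011), Sox2 was 1.23 (adjusted p = 0.098), Klf4 0.06 and Myc 0.71. Cdkn2a was lower in 3F (-0.69 ± 0.16, adjusted p = 0.0078). In limma 3646 genes passed, 1888 higher and 1758 lower in 3F. The balance turned with the scaling, to 1765 higher and 1924 lower after quantile normalization and 1688 and 2367 after median centring. With the set as a term 2772 passed, 1856 of them shared with the first fit. That fit compares 3F through its day 12 array alone, so it is no check on all 4 arrays.

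What c-Myc added was tested as 4F against 3F over the same days, 7 and 4 arrays, where days again stand in for replicates of 3F. In this comparison the arm is almost wholly tied to the set of arrays, since only the day 12 arrays of both arms belong to 1 set. Ribosomal protein genes were higher and matrix genes lower in 4F. The counts of members and the calls of single genes here come from the fit without the set. The fit with the set as a term compares 3F through its single day 12 array. Both fits, with and without the set, take the differences between arms as equal on all days, which limits both. Between 4F and GFP the difference was not equal, with pluripotency medians of 0.57 on day 8 and 1.47 between the day 12 arrays. Values with the set as a term therefore do not measure the arms alone, and a lost call there need not mean a lost difference. With the set as a term Rps3, Col1a1, Tnc, Saa3 and Pdk1 had adjusted p of 0.74, 0.87, 0.38, 0.45 and 0.67, and 14 genes passed in all. Of 31 ribosomal protein genes 17 were higher (24 over the list alone; median 0.3, adjusted p = 4e-16, 5.5e-10 with the set as a term, and 0.09 with an estimated correlation), for example Rps3 (0.5 ± 0.09, adjusted p = 0.0053). Of 38 matrix genes 26 were lower (30; median -0.98, adjusted p = 3.6e-22, 1.3e-05 with the set as a term, and 0.14 with an estimated correlation), for example Col1a1 (-0.97 ± 0.18, adjusted p = 0.0072) and Tnc (-2.23 ± 0.29, adjusted p = 0.0012). For the other lists, brackets give the count over the list alone where there is one, the median, the adjusted p, that with the set as a term and that with an estimated correlation. Inflammatory genes were lower in 11 of 32 (14; -0.72, 2.2e-07, 0.037 with the set as a term, and 0.22 with an estimated correlation), with Saa3 at -1.82, and interferon genes in 2 of 37 (0; -0.54, 2.6e-05, 1.5e-09 with the set, and 0.69), Xaf1 (-1.24) and Ddx58 (-1.18). Oxidative phosphorylation genes were higher in 10 of 37 (21; 0.27, 5.5e-11, 0.00083 with the set, and 0.14), and 1 of 19 glycolysis genes, Pdk1 (1.24), was higher (1; 0.37, 5.5e-05, 0.0011 with the set, and 0.46). Mesenchymal regulators were lower in 14 of 31 (20; -0.61, 4.8e-12, and 0.14), with Cdh11 at -1.6 ± 0.32, and contractile genes in 4 of 27 (8; -0.75, 9.7e-08, and 0.46), and neither list passed with the set as a term (0.078 and 0.55). Nucleolar genes were higher in 23 of 52 (40; median 0.6, adjusted p = 5.9e-19, and 0.34 with an estimated correlation), with Dkc1 at 1.05. That list reversed with the set as a term (-0.2, adjusted p = 0.0086), and so did the cell cycle list (0.2 with 1 of 49 higher, 0.007, and 0.88; -0.4 and 4.3e-05 with the set) and the chromatin list (0.26 with 2 of 34 higher, 0.00024, and 0.63; -0.22 and 0.00084 with the set). Pluripotency genes differed by 0.1 (adjusted p = 0.31), with 1 higher and 1 lower. With the set as a term the value was -0.44, while the day 12 arrays, which share a set, differed by -0.01. Epithelial genes differed by 0.12 (adjusted p = 0.52). The p53 list had a median of -0.01 (adjusted p = 0.89), and 0.19 with the set as a term (0.0059).

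The largest single differences between 4F and 3F were Sostdc1 (-2.3 ± 0.32, adjusted p = 0.0015), Cxcl5 (-2.4 ± 0.48, adjusted p = 0.0088), Ccn3 (-2.31) and the elastic fibre gene Mfap5 (-2.25 ± 0.34) below, and Bex1 (1.89 ± 0.34, adjusted p = 0.0053), Tfrc (1.84 ± 0.44, adjusted p = 0.02) and Ccnb1ip1 (1.73 ± 0.26, adjusted p = 0.0021) above. None of these passed with the set as a term, whereas Cdkn2a did (0.67 ± 0.16, adjusted p = 0.019, and 0.0093 with the set). Klf4 was lower in 4F (-0.7 ± 0.18, adjusted p = 0.027, and 0.9 with the set), Myc was -1.48 (adjusted p = 0.075), and Nanog 0.45 (adjusted p = 0.68). In limma 1921 genes passed, 771 higher and 1150 lower in 4F. This balance depended on the scaling, with 1049 higher and 980 lower after quantile normalization and 907 and 976 after median centring. With the set as a term 14 passed, 3 higher and 11 lower, with 6 in both fits and 1622 at an unadjusted p under 0.05. The count was 440 without 3F day 5, 591 without 3F day 8, 804 without 3F day 3 and 1239 without 4F day 5 replicate 1. Within the set that holds both day 12 arrays, 59.2% of the 3004 genes called on days 3, 5 and 8 went the same way, 47.1% of the 1436 that were higher in 4F and 70.3% of the 1568 that were lower.

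The latest time points have 1 array per arm and are given as values. On day 12 pluripotency and epithelial genes stood above GFP in both factor arms, with list medians of 1.47 and 1.72 in 4F and 1.13 and 1.34 in 3F, each at percentile 100 of 10000 random lists of like brightness. The percentiles are no test, since random genes are drawn independently, list members vary together, and there is no spread between arrays. Nanog was 3.5 above GFP in 4F and 3.34 in 3F, Dppa5a 4.95 and 4.39, Epcam 4.43 and 4.34, Pou5f1 4.28 and 4.65, and Sox2 4.16 and 3.89. Mesenchymal regulators and matrix genes stood below GFP in both (4F -1.46 and -2.43, 3F -1.08 and -1.66, each at percentile 0). Cell cycle genes were above GFP by 1.57 in 4F and 1.77 in 3F. Interferon genes were above GFP by 0.83 in 4F and 1.29 in 3F. Between 4F and 3F on day 12 glycolysis genes stood 1 higher in 4F (percentile 100) and ribosomal protein genes 0.36 higher (percentile 100). Matrix genes were at -0.64 and interferon genes at -0.53 (percentile 0), nucleolar genes at -0.24 (percentile 2.59), and pluripotency genes at -0.01 (percentile 18.3). Nanog (0.15) and Epcam (0.09) were near equal between both arms, while Cdkn2a was 1.43 and Krt8 1.16 higher in 4F, and Zeb2 was -1.5. In 3F the pluripotency median against day 0 was -0.02, -0.09, 0.08 and 1.03 on days 3, 5, 8 and 12, and in 4F it was 0.41 and 0.97 on day 8, 1.09 on day 10 and 1.28 on day 12. On day 10 of 4F the log2 signals were 9.11 for Nanog, 9.93 for Pou5f1, 9.25 for Sox2 and 9.94 for Epcam.

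**Figure D4:**
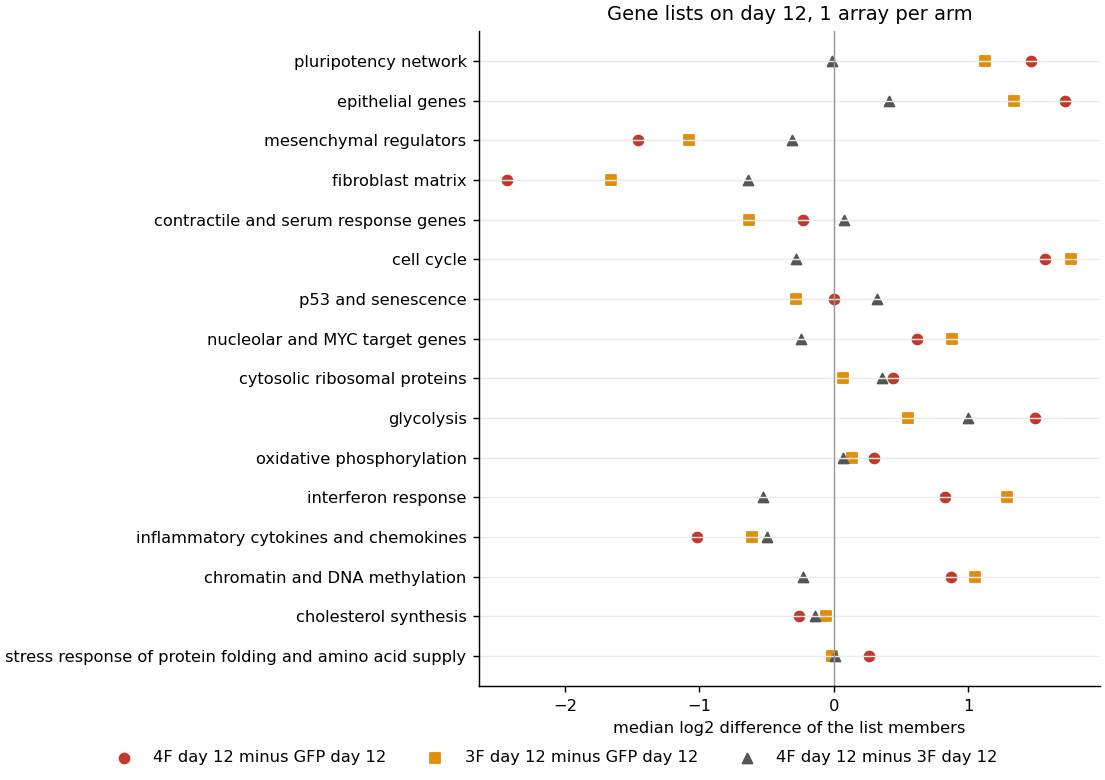
Median log2 difference of the members of 16 program lists on day 12, 1 array per arm, for 4F minus GFP (circles), 3F minus GFP (squares) and 4F minus 3F (triangles). Pluripotency genes stood at 1.47, 1.13 and -0.01.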

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

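Chosen only after the results were seen were the test of the replicate difference in pluripotency genes against random lists, both tests of the Myc signal, the separate shares of genes higher and lower in 4F than in 3F on day 12, and the fit without the replicate 2 set; the fit without the 120 ng arrays was added after the data were seen, with its bound written before its count was known.

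The difference between 4F and GFP changed from day 1 to day 8, by a test of the change itself, for 781 genes that became higher in 4F relative to GFP and 912 that became lower (limma, 2 arrays per group; the count of 1693 was 922 without 4F day 1 replicate 2). Among genes named for day 1, Anxa10 changed by -2.79, Epha7 by -1.77, Plekhh1 by 0.79, Cxcl12 by -2.76, Rspo2 by -1.36, S1pr3 by -1.56 and Itga11 by -1.75 on the log2 scale, while Akr1c18 (2.09, adjusted p = 0.068), Tek (-0.76, adjusted p = 0.27) and Tmem229b (0.05, adjusted p = 0.97) did not pass. Higher relative to GFP on day 8 than on day 1 were Bex1 (3.74), Stmn2 (3.05), Necab1 (3.45), Tfrc (2.42), Aldoc (4.43), Tdgf1 (3.19), Foxd1 (3.63), Pou5f1 (2.92), Sox2 (1.63), Nanog (1.96), Dppa5a (2.77) and Fbxo15 (2.47). Lower relative to GFP on day 8 than on day 1 were the secreted proteins Serpina3n (-5.64), Cxcl5 (-4.08), Aspn (-4.06), Dpt (-4.32), Reg3g (-4.87), Mmp13 (-4.01) and Gas6 (-4.05), the sterol hydroxylase Cyp7b1 (-3.97), the repressor Zeb1 (-1.24) and the collagens Col1a1 (-1.97) and Col3a1 (-1.87). Such differences can come from either arm: against day 0 Serpina3n and Reg3g stood at 0.06 and 0.06 in 4F and at 5.91 and 5.05 in GFP.

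The same test by lists gave median changes of -1.24 for mesenchymal regulators (17 of 31 members lower), -1.84 for matrix (28 of 38 lower), 1.25 for glycolysis, 0.48 for oxidative phosphorylation and 0.66 for chromatin genes, which also passed with an estimated correlation (adjusted p = 0.019, 0.026, 0.011, 0.019 and 0.042). Pluripotency (0.64), epithelial (0.54), cell cycle (1.32, 28 of 49 higher), nucleolar (0.5), ribosomal protein (0.29), inflammatory (-1.31) and cholesterol genes (0.87) passed with the preset correlation and not with an estimated one (adjusted p = 0.15, 0.23, 0.15, 0.17, 0.23, 0.057 and 0.24). Outside the named genes, 676 of 7064 probe sets with several symbols or none differed between 4F and GFP on day 8 (499 higher, 177 lower; 9.57%, against 27.6% of named genes).

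Pluripotency genes were higher in replicate 2 than in replicate 1 of 4F on days 5, 6 and 8, with medians of 0.14, 0.18 and 0.44 and 27, 35 and 34 of 39 members higher. On day 8 the list lay at percentile 100 of random lists matched on brightness (these spanned -0.11 to 0.1). This is no test, since random genes are drawn independently, list members vary together and each set has 1 array, so the amount of RNA labelled stays open. Whether replicate 2 may have been further along the same course stays open: across genes, which are not independent replicates, its difference correlated at r = 0.11 on day 8 and 0.16 on day 6 with the change from day 8 to day 12 in 3F, but at -0.051 on day 5. The GFP day 8 replicates set for comparison beforehand gave -0.18, and the pairs outside these days ranged from -0.19 (4F day 2) to 0.086 (GFP day 1), so the r of day 5 lies within them and those of days 6 and 8 little above. Replicate 2 also had higher interferon genes (1.38 on day 8, 36 of 37 members), so other effects of separate batches or infections stay open.

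The Myc signal was not higher in 4F than in GFP on days 1, 3, 5 and 8, while the single arrays of day 12 gave 7.52 in 4F and 6.58 in GFP. Whether the 4 factor signals register the delivered transcripts stays open. On day 1, 0 of the 4 were at least 1 higher in 4F than in GFP. This count includes Myc itself and its bound was written after the values were seen, so it does not decide. Pou5f1 (0.69) and Sox2 (0.45) lay above GFP and Klf4 (-0.43) and Myc (-0.45) below, none past the threshold. An exchange of 4F and 3F labels would need lower nucleolar genes in arrays labelled 4F, and they were higher on 3 of the 4 days (0.61, 0.87 and 1.04 on days 3, 5 and 8, -0.24 on day 12). On days 3, 5 and 8 the arms lie in different sets, so an exchange cannot be told apart from a difference between sets. A biological fall of the endogenous Myc transcript was not tested and stays open.

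The count of genes between 4F and 3F fell from 1921 to 14 with the set as a term. A difference between sets in place of arms fits part of it: 59.2% of the genes called on days 3, 5 and 8 went the same way between the day 12 arrays, which share a set, under the bound of 60% fixed before but above random lists (48.2 to 51.7%). For genes higher in 4F the share was 47.1%, within random lists (47.1 to 52.1%), while for genes lower in 4F it was 70.3%, above them (47.8 to 52.5%). Random genes are drawn independently and day 12 has 1 array per arm, so a difference between sets stays open there too. The RNA amount could contribute, since 133 genes (6.92% of 1921, under the bound fixed before) were called without the 120 ng arrays and 1220 without the replicate 2 set instead, but it cannot be separated from anything else that replicate 1 arrays share. A biological difference between arms that lessens by day 12 stays open, and list medians per array had been seen before these tests. The fit with the set as a term compares 3F through its day 12 array alone, so its low count does not tell sets from arms.

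Other splits of the same arrays within days were compared for the 3 models with enough arrays. For the mean of 4F and GFP, chance can be excluded: of 100 of the 648 splits, 1, the real one with 7464 genes, was as large. The highest other gave 6552, in which a single array of each arm was exchanged (4F day 1 replicate 2), and 34 others gave over 0. Of the 22 other splits that part as many pairs (8), the highest gave 1067 and the median was 0, and the split by set gave 58. For 4F and 3F, 1 of 54 splits was as large (real 1921, highest other 1121, in which 4F day 12 changed arms), and for 3F and GFP 1 of 54 (real 3646, highest other 536, in which all 4 3F arrays were exchanged). For both, the real split gave the most genes. All 3F arrays lie in the set without number, so outside day 12 the real split also parts the sets. A difference between sets alone could therefore make the real split the largest. The comparison of splits thus cannot exclude chance for a difference between these arms, and does not separate the arms from the sets.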

How the results depend on the processing

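Added only after the data were seen were the fits without the 120 ng arrays (its bound was written before its count was known), without the replicate 2 set, and within 1 set. Among named genes and lists 15 reversals of direction were counted under the alternatives run, all given here. For tested values a reversal was counted only where the value passed in the main or the alternative fit. Sign changes of values that passed in neither are not covered. Quantile normalization, median centring, the filter on dim genes, the mean of a gene's rows, and limma's trend and robust options left every total within 1.5 times of its value. Counts by direction moved further for GFP against day 0 on day 1 (8 higher and 10 lower; 14 and 11 with quantile normalization, 7 and 18 with centring, 5 and 7 with the mean of rows, 7 and 5 with the trend) and for 4F and GFP on day 1 (78 lower; 51 with centring). The balance of higher and lower genes turned with quantile normalization for 4F and GFP on day 5 (2327 and 2125), day 8 minus day 1 (977 and 970), 4F against day 0 on day 8 (1663 and 1653), 4F and 3F (1049 and 980) and 3F and GFP (1765 and 1924). It turned with centring for 3F and GFP (1688 and 2367), 4F against day 0 on day 6 (1356 and 1779) and GFP against day 0 on day 5 (994 and 1045), and with the trend for the mean of 4F and GFP (3670 and 3759). It turned with the set as a term for 4F and GFP on day 5 (2826 and 2787), their mean (4281 and 4389) and 4F against day 0 on day 2 (1450 and 1429), and with a change of at least 1 for 4F and GFP on day 3 (305 and 387), day 8 (976 and 1043) and their mean (363 and 527) and for 4F against day 0 on day 6 (453 and 625). The arrays of the compared groups alone turned 4F against day 0 on day 6 (1044 and 1218), and leaving out the replicate 2 set turned 3F and GFP (1431 and 1455). With the set as a term, 837 values for named genes and lists stayed on their side of the threshold, 109 lost and 20 gained a call, and 12 reversed, all in 4F against 3F: Tfrc -0.03, Slc35f2 -0.2, Jarid2 -0.09, Cdt1 -0.12, Dkc1 -0.53, Polr1b -0.29, Smarcc1 -0.09, and the lists pluripotency -0.44, cell cycle -0.4, p53 and senescence 0.19, nucleolar -0.2 and chromatin -0.22. Quantile normalization reversed Rplp1 (0.01) and Rplp0 (0.06) in 3F against GFP, and median centring reversed neural markers in 3F minus GFP on day 12 (-0.06). The cause was not tested for these.

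Counts with the set as a term were 924 (4F and GFP day 1), 3749 (day 3), 2820 (day 8 minus day 1), 369, 2879, 2733 and 3087 (4F against day 0, days 1 to 4), 143, 592 and 3446 (GFP against day 0, days 1, 3 and 5) and 14 (4F and 3F). The cause was not tested. Asking also for an absolute log2 change of at least 1 lowers counts by construction: 73, 692, 1371 and 2019 (4F and GFP days 1, 3, 5 and 8), 890 (mean), 982 (day 8 minus day 1), 74, 646, 588, 702, 948, 1078 and 1057 (4F against day 0), 7, 91, 496 and 1280 (GFP against day 0), 255 (4F and 3F) and 832 (3F and GFP). With the arrays of the compared groups alone, which leaves fewer arrays to estimate the spread, limma gave 0 (day 1; 3173 at an unadjusted p under 0.05), 760 (day 3), 2382 (day 8) and 816 (day 8 minus day 1) for 4F and GFP, 34, 984, 773 and 1091 for 4F against day 0 on days 1, 2, 3 and 8, and 0 (2118 unadjusted), 7 and 2450 for GFP against day 0 on days 1, 3 and 8. The mean of 4F and GFP gave 3121 genes within the replicate 1 set and 0 within the replicate 2 set (limma, 6024 unadjusted). Both sets hold as many arrays of these groups, and the cause of the difference between them was not tested. 4F against 3F gave 3378 in the group-mean model, 3004 on days 3, 5 and 8, 133 without the 120 ng arrays and 1220 without the replicate 2 set, and the cause was not tested. Camera with an estimated correlation, called 1 of 27 lists in place of 9 (4F and GFP day 1), 6 in place of 12 (day 8), 1 in place of 13 (4F day 8 against day 0), 1 in place of 13 (GFP day 8 against day 0), and 0 in place of 11 for 4F and 3F as for 3F and GFP; the estimate replaces the preset value of 0.01 with 1 drawn from these arrays.

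Leaving out 1 array, where the lone array left in a group is assumed to vary like the other groups, gave 23 to 308 (4F and GFP day 1), 1134 to 2384 (day 3), 2427 to 3508 (day 5), 4460 to 5020 (day 8), 6656 to 7472 (mean), 922 to 1578 (day 8 minus day 1), 29 to 61, 999 to 1238, 814 to 1209, 1088 to 1290, 1507 to 1795, 2066 to 2190 and 1958 to 2708 (4F against day 0, days 1, 2, 3, 4, 5, 6 and 8), 3 to 42, 6 to 571, 683 to 1282 and 2747 to 3821 (GFP against day 0, days 1, 3, 5 and 8), 440 to 2848 (4F and 3F) and 2442 to 3967 (3F and GFP). Leaving out all 7 arrays without a replicate number changed no count, since their groups add no residual degrees of freedom (4F and GFP days 1, 3, 5 and 8: 361, 2378, 4265 and 5497, mean 7464, day 8 minus day 1 1693; 4F against day 0: 167, 1864, 1700, 2007, 2702, 3214 and 3169; GFP against day 0: 18, 210, 2108 and 4006). Of the values of named genes and lists in the fits without 1 array, 5624 kept their side of the threshold, 732 lost and 24 gained a call. Array signal near the background limits dim genes, and 4639 of the genes fell under the filter.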

Other observations

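Interferon response genes differed more between replicates than between arms in places. Their median in replicate 2 exceeded that in replicate 1 by 1.03, 1.81 and 1.38 in 4F on days 5, 6 and 8, with 35, 36 and 36 of 37 members higher, and by 0.31 in GFP on day 8. Against day 0 the medians of the unnumbered set were 1.46 and 1.27 in 4F on days 10 and 12, -0.07, 0.5, 1.61 and 1.96 in 3F on days 3, 5, 8 and 12, and 0.51 in GFP on day 12.

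Cell cycle genes differed between replicates in both directions: all 49 were lower in replicate 2 of 4F on day 2 (median -0.43) and of GFP on day 5 (-0.49), and 45 of 49 were higher in replicate 2 of GFP on day 8 (0.68). The Myc signal of the GFP day 8 arrays was 7.15 and 9.72. Glycolysis genes stood at 0.73 and 0.68 against day 0 in 4F on days 10 and 12, and at -0.3, -0.34, -0.27 and -0.02 in 3F on days 3, 5, 8 and 12.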
